A study of Mus musculus with 12 samples.

How the data were processed

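Whole aortas of male C57BL/6J mice, an inbred laboratory strain, were collected at 4, 26 and 86 weeks of age, with arch, ascending, descending, thoracic and abdominal parts pooled after the perivascular fat had been dissected away, per the labels' protocols. Single-cell RNA libraries and single-nucleus ATAC libraries were made with droplet kits. ATAC-seq reads out open chromatin as the sites at which a transposase could insert adapters. There were 12 libraries, 2 per age and assay. The study's design text gives 2 mice per age, so libraries of 1 age and assay were treated as separate mice.

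Per the submitters' processing notes, RNA reads were counted with Cell Ranger 3.1.0 and analysed with Seurat 3.1.4, and ATAC reads were processed with Cell Ranger ATAC 1.2.0 and Signac 0.2.4, on the mouse build mm10. The roles of these tools within the pipeline and the counting annotation are not given in the sources used here. The deposited RNA matrices hold UMI counts per gene and barcode with no normalization, for 31053 genes. 5 of the 6 were already restricted to 5220 to 7203 barcodes, and the matrix of 4-week replicate 1 listed 6794880 barcodes, of which 1618376 had a UMI. The authors also deposited a table with a cell type, given as 1 of 16 labels, for 28014 barcodes. Cells in that table had at least 501 genes and under 10% mitochondrial UMIs. A merged table of the same cells that the authors deposited held 19266 of the genes, 16449 of them with equal sums in all samples. Of 115596 gene sums per sample, 6246 differed, and each of these was 0 in the merged table with at most 4 cells holding a UMI in the matrix. The matrices were used. The deposited ATAC files hold 1 peak list per library, called separately, and a count of cut sites or fragments per peak and cell. The count matrices of 26-week replicate 1 and of both 86-week libraries were used, and those of the other 3 libraries were not analysed here.

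Cells carried the authors' labels and were merged by name into 14 classes. The labels VSMC, Fibroblast and Monocyte became smooth muscle cells, fibroblasts and macrophages, and MacroEC, MicroEC and LymphoEC became endothelial cells. UMI counts of all cells of a class were summed per mouse, so that the mouse and not the cell was the replicate. A class was tested where every mouse held at least 20 of its cells. Sums were compared with the quasi-likelihood test of edgeR 4.0.16 (TMM scaling, expression filter by age, robust dispersions), with age as the factor and all 6 mice in a fit with 3 residual degrees of freedom. P-values were adjusted with the Benjamini-Hochberg method over the genes tested, at a threshold of 0.05. CPM values are TMM-scaled and relative to the summed UMIs of the class, and log2 fold changes are given with SE. DESeq2 1.42.0 served as the other tool. For a gene without a UMI in both mice of an age, the fold was computed against 3 counts over both mice and is a lower bound from counting error only.

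Before the data were examined, 46 gene lists were fixed, 15 of them markers of cell types, and were tested with camera in limma 3.58.1 on voom values with an inter-gene correlation of 0.01, for lists with at least 5 tested members. Camera was run again with the correlation estimated from the data, and no list in any class or comparison passed at 0.05 in that run. That run also tests on the 3 residual degrees of freedom, so it differs from the first in more than the correlation. List members were counted by the edgeR result over all genes and, separately, with the adjustment over the list alone. The differences between classes in the change from 4 to 86 weeks were tested in edgeR as a class-by-age interaction with the mouse as a fixed effect. Shares of classes were tested over the 3 ages with a two-sided exact Jonckheere-Terpstra test over the 90 assignments of 6 mice to 3 ages, whose smallest possible p is 0.0222. Intervals of single shares are 95% Clopper-Pearson intervals and cover counting error only. Peak lists were compared by the Jaccard index, the bases shared by 2 lists over the bases covered by either, with an exact permutation of the pairing of the 6 libraries. Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly behind mm10, in which 25723 of 31053 genes were found by symbol or synonym. That table gives no strand, so peaks within 1000 bases of either end of a gene were taken as its promoter peaks. Their counts were scaled to the total of the matrix, and medians over gene lists were set against 10000 random lists matched on accessibility in 20 bins, with a pseudocount of 1 CPM and a mean count of at least 20. ATAC cells were not assigned to classes.

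The genes named in the text followed a rule fixed before the data were examined. It took genes with an adjusted p under 0.05, both mice of 1 age above both of the other, and a mean of at least 30 CPM. Of these it took the 10 rising and 10 falling genes with the largest fold changes from 4 to 86 weeks, and 5 and 5 for the other comparisons. It also took the 4 members with the smallest p of each described list, the markers of each class, the 5 largest differences in each direction between classes, and peaks at named genes. Names that are only predicted loci were counted and not named, and some genes that the rule took are not reported here. Tests of the MacroEC label alone, of T cells and of B cells were added after the data had been seen.

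Replicates of 1 age differed beyond counting noise in all 4 main classes. Chi-square over its degrees of freedom was 4.19 to 45.7 over genes with at least 20 UMIs. The edgeR and camera steps were tested on simulated counts drawn from the real means, library sizes and dispersions, and DESeq2 was not. The edgeR simulations held 200 changed genes, and the camera simulation held 1 list raised 2-fold. For smooth muscle cells from 4 to 86 weeks, 48% of genes changed 4-fold and 3.09% of genes changed 2-fold were recovered among 11322 tested. For fibroblasts these were 78% and 48.5% of 12954, for endothelial cells 72.2% and 10.1% of 11637, and for macrophages 69.7% and 8.16% of 11708. False calls made up 5.56%, 14.9%, 19.2% and 12.5% of the calls in these 4 simulations. The interaction of smooth muscle cells and fibroblasts recovered 34% of 4-fold and 0% of 2-fold changes among 11261 genes, with 17.5% false calls. In the camera simulation the raised list had an adjusted p of 1.8e-48, and 1 unchanged list of 45 was called too. Correlation between genes was not among the inputs named above, so the camera simulation cannot check the preset inter-gene correlation. It gives no rate of false list calls for the real data. Scanpy's Scrublet, set to an expected 6% of doublets, called at most 9 cells per mouse by its automatic threshold and so had not separated doublets. An alternative without the cells of the highest scores, 5.04% to 5.97% per mouse, was run in its place.

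The alternatives were 103 planned and 28 added after the data had been seen. They covered DESeq2, RLE scaling, no expression filter, the replicate number as a block, sums thinned to the lowest, each library left out, doublet removal, cells of at least 3000 UMIs, estimated correlations, overlap rules for peaks and distances around genes. To compare shares of cells with a UMI, each cell was thinned at random to 2000 UMIs and shallower cells were left out. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3 were used.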

Results

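The aorta, the main artery leaving the heart, was profiled in young, adult and old mice by single-cell RNA sequencing and by single-nucleus ATAC-seq. The series addressed how the cells of the aortic wall change in gene expression and in open chromatin with age. Each assay had 2 libraries at 4, 26 and 86 weeks. The RNA libraries held 5887 and 4783 annotated cells at 4 weeks, 5095 and 5097 at 26 weeks, and 2907 and 4245 at 86 weeks, with totals of 36122541, 35015048, 46883105, 43780698, 31157218 and 35041056 UMIs. Of these 28014 cells, 12139 carried vascular or other non-immune labels and 15875 carried immune labels. The median UMI count per cell was 3780 in 4-week replicate 1 and 9165 in 86-week replicate 1, and lay between 5031 and 6595 in the other 4 mice. The ATAC libraries held 4140 and 4810 cells at 4 weeks, 4731 and 9055 at 26 weeks, and 3176 and 3532 at 86 weeks.

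The first comparison asked how the makeup of the recovered cells differed with age. Smooth muscle cells, the contractile cells of the aortic media, made up 7.31% ± 1.5 (SD, n = 2) of cells at 4 weeks, 4.76% ± 3.26 at 26 weeks and 1.16% ± 0.603 at 86 weeks. Neutrophils made up 0.158% ± 0.103, 1.99% ± 1.12 and 4.24% ± 4.27, and plasma cells, the antibody-secreting cells, 0.715% ± 0.0942, 1.63% ± 0.777 and 2.73% ± 0.939. Fibroblasts were at 26.4% ± 15.4 at 4 weeks and 21.3% ± 15.5 at 86 weeks, endothelial cells at 12.6% ± 3.75 and 19.6% ± 9.07, and macrophages at 8.33% ± 0.517 and 15.7% ± 7.07. None of the 14 classes passed the two-sided exact Jonckheere-Terpstra test over the ages, in which the smallest p that 6 mice allow is 0.0222. The smallest p, 0.0667, was reached by smooth muscle cells, neutrophils and plasma cells, and was 0.311 after Benjamini-Hochberg adjustment over the classes. Mice of 1 age differed widely. B cells were 4.33% of the cells of 86-week replicate 1 (95% interval 3.62 to 5.14, Clopper-Pearson, counting error only) and 35.7% of those of replicate 2 (34.3 to 37.2). Among non-immune cells alone, smooth muscle cells were 16.1% at 4 weeks and 2.78% at 86 weeks (exact test, p = 0.0667).

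**Figure D1:**
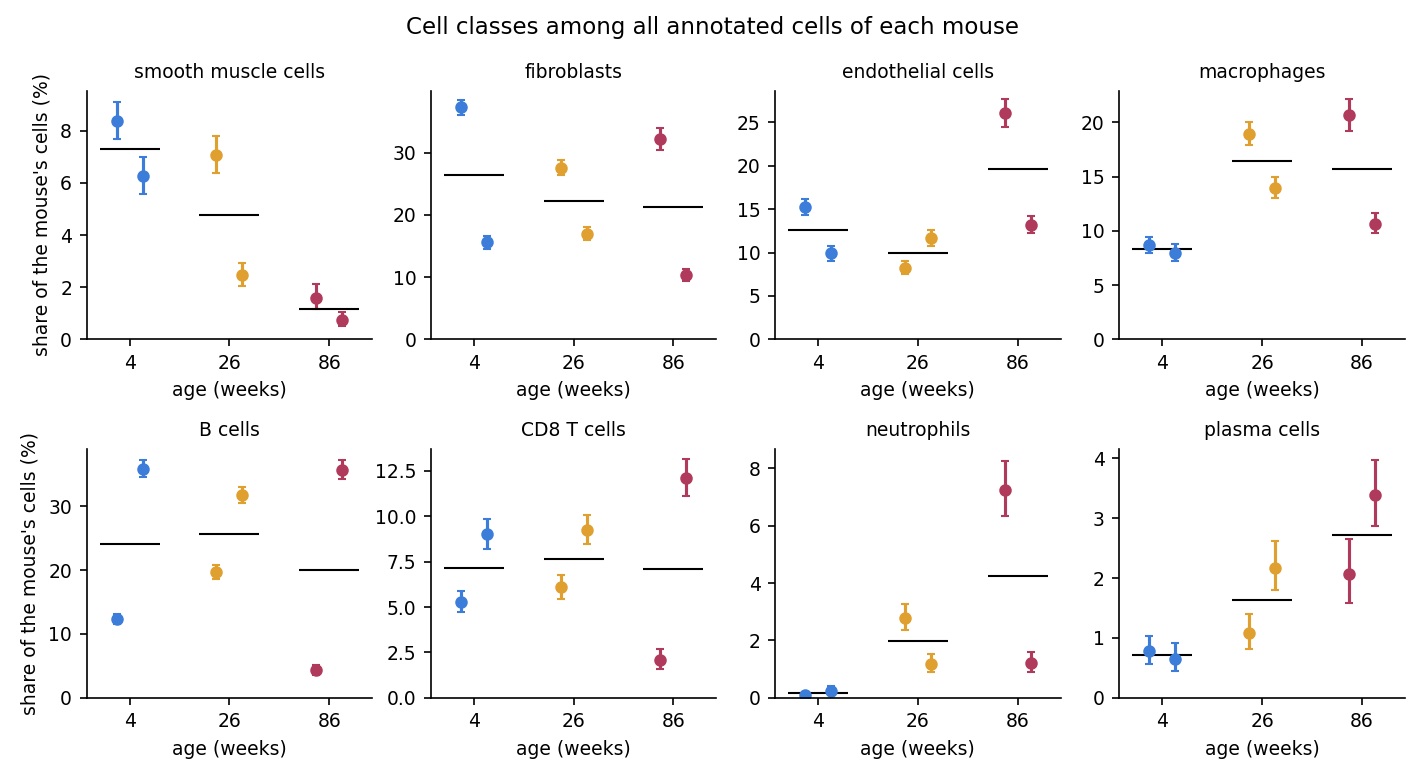
Share of each of 8 cell classes among the annotated cells of a mouse (y axis, percent) against age (x axis, weeks). Points are single mice with 95% Clopper-Pearson intervals and black lines are means of 2 mice; the smooth muscle mean lies at 7.31% at 4 weeks and 1.16% at 86 weeks.

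The next comparison asked which genes differed with age in smooth muscle cells, first between 4 and 86 weeks. Transcripts of the contractile apparatus were lower at 86 weeks. Acta2, smooth muscle actin, fell with a log2 change of -3.42 ± 0.28 (SE; edgeR, adjusted p = 0.000687), Myh11, smooth muscle myosin, of -2.76 ± 0.26 (adjusted p = 0.000918), Tagln, an actin-binding protein, of -2.91 ± 0.23 (adjusted p = 0.000636) and Actn1, an actinin, of -3.89 ± 0.26 (adjusted p = 0.000461). Of 22 tested members of the contractile list, 18 fell, 0 rose and 4 did not pass, and 20 fell and 1 rose adjusted over the list alone (median log2 change -2.58, camera adjusted p = 5.64e-20; adjusted p = 0.549 with an estimated correlation). Eln, which encodes elastin, the protein of the elastic lamellae, fell with a log2 change of -5.80 ± 0.36 (adjusted p = 0.000461), and 10 of 20 members of the elastic fibre list fell with it, 12 adjusted over the list alone. Among them were Lox (-3.47) and Loxl1 (-2.21), enzymes that crosslink elastin, and Ltbp1 (-2.70). The list's median was -1.59, or -1.44 with 1 member without counts at its bound (adjusted p = 1.4e-05; adjusted p = 0.549 with an estimated correlation).

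Sost (ENSMUSG00000001494, chromosome 11, 101962458 to 101967015, mm10), which encodes the secreted Wnt antagonist sclerostin, was at 790 ± 230 CPM (SD, n = 2) at 4 weeks and 838 ± 335 CPM at 26 weeks. It had no UMI in either 86-week mouse, which made it at least 119-fold lower than at 4 weeks against a floor of 3 counts over both mice (edgeR, adjusted p = 0.00147). A Sost UMI was found in 57.2% and 79.3% of the smooth muscle cells of the 4-week mice, 72.8% and 46.4% at 26 weeks, and 0 of 46 and 0 of 31 cells at 86 weeks. After thinning to 2000 UMIs these shares were 48.3%, 62.8%, 66.2%, 31.9%, 0% and 0%, with 143, 30, 88, 9, 18 and 5 cells left out, which left 28 and 26 cells at 86 weeks. In B cells, which should lack the transcript, the shares before thinning were 0.551%, 0.408%, 0.9%, 0.247%, 0.794% and 0% in the same order of mice. The 0.794% of 86-week replicate 1 came from 126 B cells. After thinning the B-cell shares were 0.063% to 0.318% in the younger mice and 0% in both 86-week mice. Median depths were 9355, 15170, 14410, 12052, 3580 and 6306 UMIs in smooth muscle cells and 3776 to 9712 in B cells. Vcan, the proteoglycan versican, and Igsf9b were at least 22.7-fold and 19.9-fold lower, again with no UMI at 86 weeks. Sema3d, a secreted semaphorin, Xk, Gpsm2 and Ccdc42 were at least 8.70-fold, 7.68-fold, 7.24-fold and 6.96-fold lower. Cbr2 and Kcnmb1, a subunit of a calcium-activated potassium channel, fell from 248 and 210 CPM to 2.12 CPM each (log2 changes -6.78 and -6.54), which rests on 1 UMI each at 86 weeks.

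Other transcripts were higher at 86 weeks. Ednrb, an endothelin receptor, rose from 37.6 ± 11.8 to 794 ± 265 CPM (log2 change 4.40 ± 0.73, adjusted p = 0.0264). Dlk1, an imprinted gene of the Notch ligand family, rose from 3.32 to 101 CPM (4.90 ± 0.49, adjusted p = 0.0011), and Gdf15, a stress-induced cytokine, from 4.11 to 105 CPM (4.65 ± 0.58, adjusted p = 0.00456). Stc1, Tnfaip2, Myc, Fam107b, Ass1, Kcne4 and Pde4c also rose, with log2 changes of 3.46 to 5.10 (Myc 3.98, and 2.32 without 86-week replicate 1; not called in 5 of 6 runs that left out 1 mouse). Markers of pericytes, the mural cells of small vessels, moved with these genes. Of 10 pericyte markers 5 rose and 1 fell, 9 and 1 adjusted over the list alone (median 2.46, adjusted p = 1.38e-05; adjusted p = 0.644 with an estimated correlation), including Abcc9 (2.26 ± 0.28), Rgs5 (1.74 ± 0.24) and Pdgfrb (1.87), while Cspg4 fell (-1.58). Of 9 endothelial markers 2 rose, Esam (2.68) and Fabp4 (2.95), with the same count adjusted over the list alone (adjusted p = 0.00571; adjusted p = 0.644 with an estimated correlation). Of 18 MHC class I genes, which present peptides to T cells, 5 rose and none fell, 8 adjusted over the list alone, with H2-D1 at 1.62 and Tap2 at 1.39 (median 1.47, adjusted p = 1.38e-05; adjusted p = 0.644 with an estimated correlation). Fibrillar collagens fell in 5 of 12 members, also 5 adjusted over the list alone, led by Col1a1 (-3.22) and Col3a1 (-2.84; list adjusted p = 0.00819; adjusted p = 0.644 with an estimated correlation). Basement membrane genes fell in 7 of 16, with 8 falling and 2 rising adjusted over the list alone, led by Col4a5 (-5.68) and Col18a1 (-3.99; list adjusted p = 0.00228; adjusted p = 0.586 with an estimated correlation).

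Over all 11576 genes tested, 1276 differed between 86 and 4 weeks, 412 higher and 864 lower, with edgeR. DESeq2 gave another split, 755 higher and 842 lower. The 86-week sums came from 46 and 31 cells with 196078 and 203451 UMIs, against 1695013 to 4898272 UMIs in the other mice. Cells with at least 30 pericyte-list UMIs per 10000 made up 31.4% and 25.4% of the smooth muscle cells at 4 weeks, 26.7% and 51.2% at 26 weeks, and 69.6% and 93.5% at 86 weeks (34.6%, 27.1%, 30.5%, 55.2%, 85.7% and 96.2% after thinning). From 20 to 40 such UMIs, near that limit, were found in 53, 22, 49, 25, 2 and 3 of the cells before thinning. The median contractile-list UMIs per 10000 were 571, 737, 662, 577, 74.3 and 85.7 in smooth muscle cells, and 31.1 to 54.0 in cells labelled pericytes. The pericyte label held only 1 to 30 cells per mouse, and its cells also carried the endothelial genes Pecam1 and Cdh5. Within the pericyte-list cells alone 359 genes were called, 338 of them also called in all cells, and 1239 among as many cells drawn at random. The count was 559 without 4-week replicate 1, 312 without 4-week replicate 2, 724 without 86-week replicate 2 and 2482 with no expression filter.

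**Figure D2:**
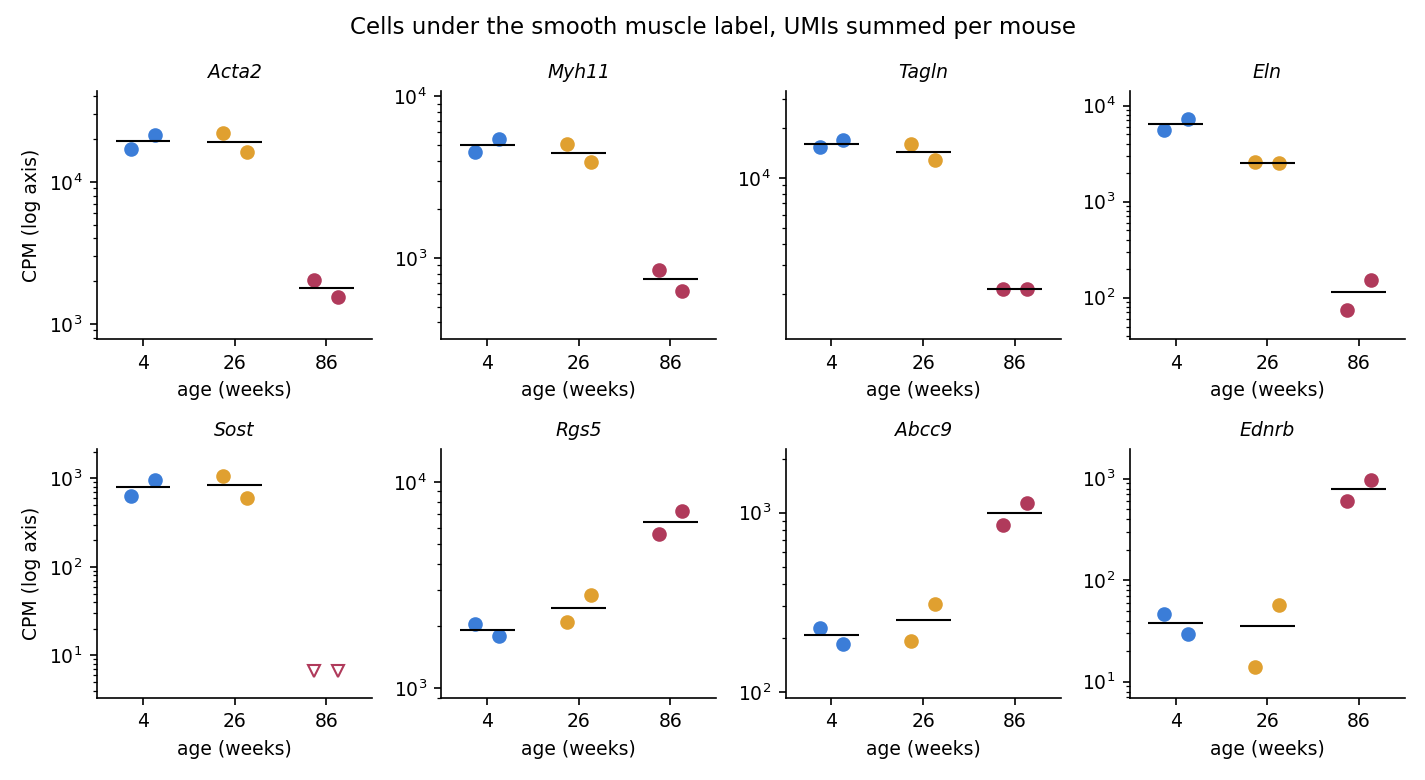
TMM-scaled CPM (y axis, log scale) of 8 genes in the summed smooth muscle cells of each mouse against age (x axis, weeks). Points are single mice and lines are means of 2; open triangles for Sost mark mice without a UMI, drawn at the floor of 3 counts over both mice (6.62 CPM).

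Between 4 and 26 weeks few genes differed in smooth muscle cells. Col4a5, a chain of basement membrane collagen, fell from 682 ± 95.5 to 195 ± 13.1 CPM (log2 change -1.80 ± 0.18), Trp53inp1, a p53 target, from 210 ± 11.5 to 65.5 ± 7.31 CPM (-1.67 ± 0.18), and Glul, glutamine synthetase, from 158 ± 5.48 to 62.9 ± 0.0878 CPM (-1.33 ± 0.15). Cxcl2, a neutrophil-attracting chemokine, rose with a log2 change of 5.04 ± 0.50. It was below the expression level of the naming rule and was chosen after its values were seen. All 4 had an adjusted p of 0.0389. Of 16 basement membrane genes only Col4a5 fell, and 5 fell adjusted over the list alone (median -0.57, camera adjusted p = 2.24e-06; adjusted p = 0.615 with an estimated correlation). Of 22 chemokine and cytokine genes 1 rose, and 3 adjusted over the list alone, with Cx3cl1 at 3.41 and Cxcl10 at 3.57 (adjusted p = 1.66e-05; adjusted p = 0.787 with an estimated correlation). Of 9 adipocyte markers none was called and 3 fell adjusted over the list alone (median -1.76, adjusted p = 0.00145; adjusted p = 0.787 with an estimated correlation). Col4a5, Trp53inp1 and Glul were no longer called when any 1 of the 4-week or 26-week mice was left out. The 4 genes were called among 11576. The count was 0 without either 4-week mouse, 2 without 26-week replicate 2, 13 without either 86-week mouse, 72 with DESeq2 and 384 with no expression filter.

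Between 26 and 86 weeks, 992 genes differed in smooth muscle cells, 288 higher and 704 lower at 86 weeks (599 and 737 with DESeq2). Sost was at least 127-fold lower at 86 weeks (adjusted p = 0.00195), Vcan at least 21.8-fold, Sema3d at least 11.8-fold, Igsf9b at least 9.96-fold and Gpsm2 at least 9.73-fold lower. Acer2, an alkaline ceramidase, rose from 5.87 ± 5.64 to 152 ± 91.4 CPM (log2 change 5.08 ± 0.75, adjusted p = 0.0157), and Ednrb, Ass1, Stc1 and Dlk1 rose with log2 changes of 4.61, 4.26, 4.02 and 3.69 (Stc1 2.46 without 86-week replicate 2; not called in 4 of 6 runs that left out 1 mouse). The contractile list fell in 18 of 22 members, with 20 falling and 1 rising adjusted over the list alone (median -2.50, camera adjusted p = 2.47e-21; adjusted p = 0.639 with an estimated correlation). In the elastic fibre list 7 of 20 fell and 1 rose, with 11 and 1 adjusted over the list alone, led by Eln (-4.48 ± 0.35; list adjusted p = 0.000235; adjusted p = 0.639 with an estimated correlation). Pericyte markers moved as well, with 2 of 10 rising and 1 falling, 7 and 1 adjusted over the list alone (median 2.10, adjusted p = 1.1e-05), and so did endothelial markers, with 2 of 9 rising, 7 adjusted over the list alone (median 3.34, adjusted p = 0.000965), and adipocyte markers, with 1 of 9 rising in both counts (adjusted p = 0.0123). With an estimated correlation these 3 had an adjusted p of 0.678. The count was 568 and 536 without 4-week replicates 1 and 2, 440 without 26-week replicate 1, 539 without 86-week replicate 2 and 2219 with no expression filter. Among pericyte-list cells it was 299.

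In fibroblasts, the matrix-producing cells of the outer wall, transcripts of matrix proteins were lower at 86 than at 4 weeks. For Col1a1 and Col3a1 most of this fall was already present at 26 weeks, as given below. Eln (ENSMUSG00000029675, chromosome 5, 134702595 to 134747368, mm10) fell from 3162 ± 63.9 CPM (SD, n = 2) at 4 weeks to 444 ± 4.30 at 26 weeks and 117 ± 1.13 at 86 weeks (86 vs 4 weeks, log2 change -4.75 ± 0.11 SE, edgeR adjusted p = 1.83e-05). Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), a chain of type I collagen, fell from 12190 ± 1921 to 1189 ± 30.8 CPM (-3.36 ± 0.25, adjusted p = 0.00485). Sparc, a collagen-binding protein, fell from 16480 ± 516 to 2505 ± 26.8 CPM (-2.72 ± 0.17, adjusted p = 0.00223) and Col3a1 from 13850 ± 1565 to 2662 ± 192 CPM (-2.38 ± 0.15, adjusted p = 0.00234). Peg3, a paternally expressed imprinted gene, fell from 257 to 21.1 CPM (-3.63 ± 0.20), and Cpz, Hhip, Itm2a, Col4a5 and Pdgfrl fell with log2 changes of -3.45 to -2.39. Among the named genes the largest rise was that of Sult1e1, estrogen sulfotransferase, from 11.8 ± 0.248 to 171 ± 68.0 CPM (3.84 ± 0.30, adjusted p = 0.00533). Serpine2, a protease inhibitor, rose from 64.0 to 348 CPM (2.45 ± 0.19), Has1, a hyaluronan synthase, from 109 to 581 CPM (2.42 ± 0.27), and Il6, an inflammatory cytokine, from 47.8 ± 21.3 to 212 ± 68.8 CPM (2.14 ± 0.37, adjusted p = 0.0436). Tnfaip2, Adm, Opcml, Pla1a, Comp and Efemp1 rose with log2 changes of 1.68 to 2.33.

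Of 13 fibrillar collagen genes tested in fibroblasts, 8 fell and none rose between 4 and 86 weeks, 9 and 1 adjusted over the list alone, with Col1a2 at -2.24 and Col5a1 at -1.45 (median -1.04, camera adjusted p = 2.55e-08; adjusted p = 0.542 with an estimated correlation). Imprinted growth genes fell in 5 of 17 and rose in 1, with 10 and 1 adjusted over the list alone, Meg3 at -1.05 and Ndn at 0.70 (adjusted p = 0.000323; adjusted p = 0.542 with an estimated correlation). In the elastic fibre list 4 of 21 fell and 1 rose, with 10 and 4 adjusted over the list alone. Mfap4 (-2.36) and Mfap2 (-1.70), microfibril proteins, fell and Efemp1 (1.68) rose (adjusted p = 0.00613; adjusted p = 0.817 with an estimated correlation). Of 25 chemokine and cytokine genes 5 rose and none fell, 9 adjusted over the list alone, among them Ccl11 (1.49) and Cx3cl1 (2.02; list adjusted p = 0.00569; adjusted p = 0.869 with an estimated correlation). Of 11 genes of the growth hormone and IGF list 3 fell and 2 rose, 7 and 2 adjusted over the list alone, with Igf1 at -1.03 and Igfbp4 at 0.93 (adjusted p = 0.0332; adjusted p = 0.817 with an estimated correlation). Smooth muscle markers were lower too, with 1 of 10 falling, 3 adjusted over the list alone (median -1.62, adjusted p = 0.00124; adjusted p = 0.817 with an estimated correlation). Without a called member, log2 changes were negative in 10 of 10 endothelial markers (adjusted p = 0.0102; 0.884 with an estimated correlation) and 8 of 8 markers of T and NK cells (adjusted p = 0.00433; 0.869 with an estimated correlation). Matrix transcripts in the B cells, a measure of free RNA, went the same way. Eln was at 44.9 CPM in B cells at 4 weeks and 3.92 at 86 weeks, and Col1a1 at 144 and 1.91 CPM.

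Of 13140 genes tested in fibroblasts, 537 differed between 86 and 4 weeks, 279 higher and 258 lower. Leaving out a young or adult mouse lowered the count to 84 without 4-week replicate 1, 184 without 4-week replicate 2, 267 without 26-week replicate 1 and 275 without 26-week replicate 2, while DESeq2 gave 841 and no expression filter 1186. Fibroblasts of 4-week replicate 1 had a median of 1889 UMIs against 8376 to 10948 in the other mice.

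**Figure D3:**
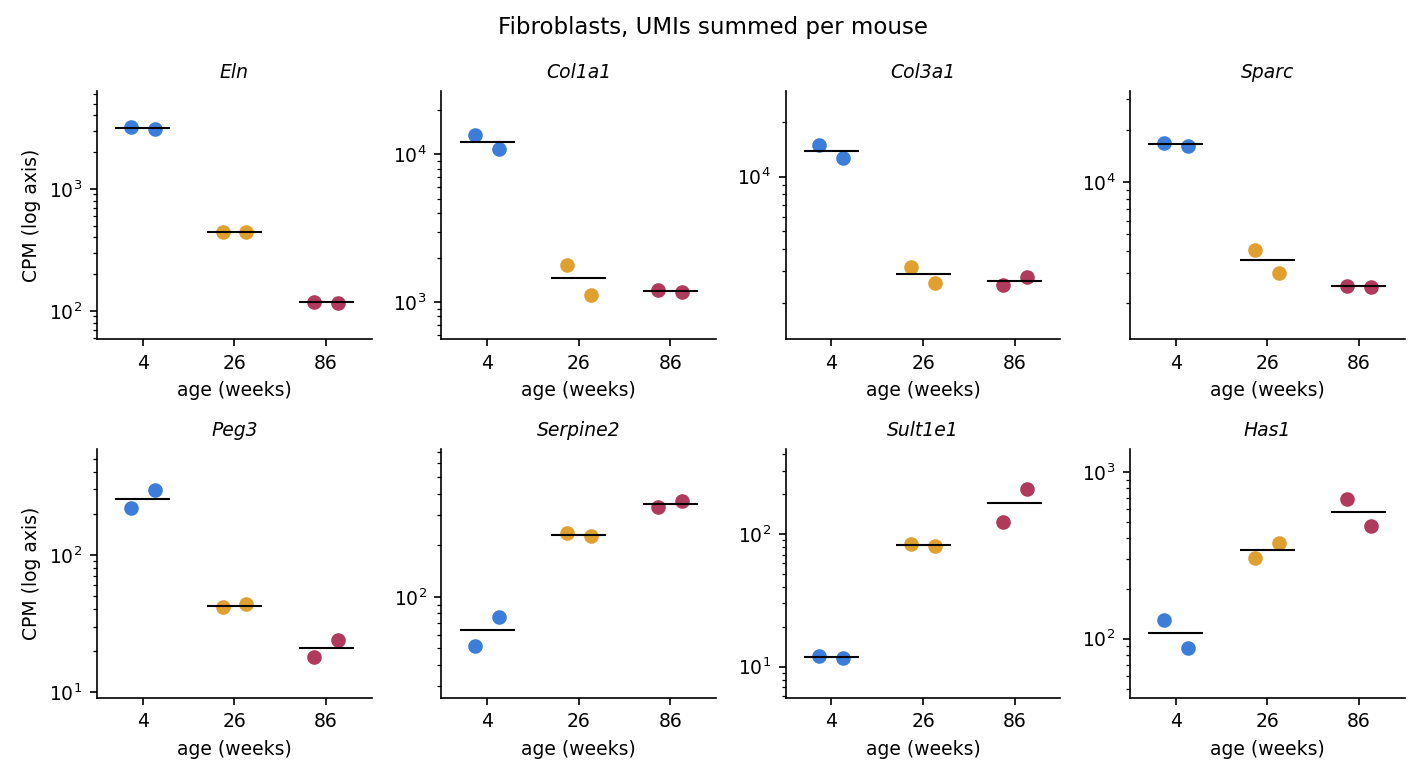
TMM-scaled CPM (y axis, log scale) of 8 genes in the summed fibroblasts of each mouse against age (x axis, weeks). Points are single mice and lines are means of 2; Eln lies at 3162 CPM at 4 weeks, 444 at 26 weeks and 117 at 86 weeks.

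At 26 weeks, 211 genes differed from 4 weeks in fibroblasts, 97 higher and 114 lower. Col1a1 fell with a log2 change of -3.07 ± 0.25 (edgeR, adjusted p = 0.00862), Eln of -2.83 ± 0.10 (adjusted p = 0.000339), Cpz of -3.29 ± 0.31, Peg3 of -2.60 ± 0.19 and Tsc22d3, a glucocorticoid-induced gene, of -3.18 ± 0.29. Sult1e1 (2.80), Serpine2 (1.86), Gsta3, a glutathione transferase (1.82), Aox3, an aldehyde oxidase (1.65), and Has1 (1.65) rose. Fibrillar collagens fell in 9 of 13 members, also 9 adjusted over the list alone, with Col1a2 at -2.12 and Col3a1 at -2.26 (median -1.03, camera adjusted p = 3.4e-10; adjusted p = 0.422 with an estimated correlation). Chemokines and cytokines rose in 4 of 25 members, 11 adjusted over the list alone (adjusted p = 1.61e-06; adjusted p = 0.695 with an estimated correlation). No marker of other cells was called, but log2 changes were negative in 9 of 9 adipocyte (median -2.79, adjusted p = 0.000297), 10 of 10 endothelial (median -1.78, adjusted p = 0.00128) and 8 of 8 T and NK cell markers (median -1.84, adjusted p = 0.00912; the 3 at 0.695 to 0.776 with an estimated correlation). Between 26 and 86 weeks 2 genes were called, with 1629 at an unadjusted p under 0.05. Eln fell further (-1.92 ± 0.10, adjusted p = 0.00429), and Wee1, a kinase that inhibits mitotic entry, rose (1.68, adjusted p = 0.0488; below the expression level of the naming rule and chosen after its values were seen). The first count was 22 and 86 without 4-week replicates 1 and 2, 16 and 6 without 26-week replicates 1 and 2, 383 and 385 without 86-week replicates 1 and 2, 546 with DESeq2 and 772 with no expression filter. The second was 38 and 101 without 86-week replicates 1 and 2, 204 with DESeq2 and 383 with no expression filter.

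In endothelial cells, which line the vessels, no gene was called over all 11826 tested in any pair of ages with edgeR. For 86 vs 4, 26 vs 4 and 86 vs 26 weeks, 1928, 653 and 1876 genes had an unadjusted p under 0.05, the smallest adjusted p were 0.0935, 0.122 and 0.0571, DESeq2 called 275, 57 and 307 genes and edgeR with no expression filter 114, 13 and 153. The class joined 3 labels whose proportions differed between mice. Under the MacroEC label Cd36 was higher and Vwf lower than under the MicroEC label, the reverse of what the names say. MacroEC cells, the most numerous label, used here as the authors gave it, were tested alone after the data had been seen, and 966 of 11024 genes differed between 86 and 4 weeks, 490 higher and 476 lower. Akap12, a scaffold protein of kinase A, rose from 150 ± 7.90 to 1027 ± 135 CPM (log2 change 2.78 ± 0.19, adjusted p = 0.000257), and Rbp7, a retinol-binding protein, from 576 ± 137 to 2272 ± 5.95 CPM (1.98 ± 0.20, adjusted p = 0.00139). Spry4 (3.36 ± 0.29), Dusp6 (2.08 ± 0.26) and Dusp8 (2.94 ± 0.47), feedback inhibitors of MAP kinase signalling, rose, as did Lrrc32, Maff, Creb5, Nes and Plaur, with log2 changes of 1.97 to 2.88. Rsad2, an antiviral interferon-stimulated gene, fell from 493 ± 168 to 146 ± 28.1 CPM (-1.75 ± 0.27, adjusted p = 0.0131) and Igfbp3, an IGF-binding protein, from 130 ± 24.4 to 39.2 ± 4.61 CPM (-1.74 ± 0.16, adjusted p = 0.00102). Stk17b, S1pr4, Pik3ip1, Hist1h1c, Ccdc28b, Tril, Trp53inp1 and Sult1a1 fell with log2 changes of -1.94 to -1.60.

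Of 29 genes of endothelial function and arterial identity tested in MacroEC cells, 5 rose and none fell, 12 and 1 adjusted over the list alone (median 0.45, camera adjusted p = 0.000892; adjusted p = 0.966 with an estimated correlation). Ednrb (1.27) and the flow-responsive factors Klf4 (1.43) and Klf2 (0.95) rose. Given its Cd36 and Vwf levels, the label does not settle whether these cells line large vessels. Of 30 interferon-stimulated genes 7 fell and none rose, 12 adjusted over the list alone, with Gbp2 at -0.90 and Parp14 at -0.54 (median -0.40, adjusted p = 0.00407; adjusted p = 0.966 with an estimated correlation). Markers of other cells moved too. Of 5 striated muscle markers 4 fell, 5 adjusted over the list alone, with Acta1 at 50.8 and 39.4 CPM in the 4-week mice and 0 and 0.537 CPM in the 86-week mice (list adjusted p = 0.000696). Without a called member, log2 changes were negative in 10 of 10 fibroblast markers (median -1.71, adjusted p = 0.0285) and 9 of 10 B-cell markers (median -1.77, adjusted p = 0.0456), and positive in 7 of 7 erythroid markers (median 1.96, adjusted p = 0.0285). With an estimated correlation all 4 had an adjusted p of 0.966. Between 26 and 4 weeks 137 genes were called, 46 higher and 91 lower, with Odc1 (1.70), Sncg (1.54), Ralgds, Pde4b and Nrep rising, and Bcl2l1, an inhibitor of apoptosis (-2.39), Hipk1 (-1.84), Zfp946, Max and Rassf4 falling. Between 86 and 26 weeks 1026 were called, 568 higher and 458 lower, with Fkbp5 (3.34), Maff (3.12), Spry4, Pmp22 and Bcl2l1 (2.55) rising, and the apelin receptor gene Aplnr (-2.58), Cyp2e1, Rsad2 (-2.11), Bok and Tnfsf10 falling. The number of genes changed in MacroEC cells, 86 vs 4 weeks, was 478 without 4-week replicate 2, 640 without 26-week replicate 2, 376 and 443 without 86-week replicates 1 and 2 and 2089 with no expression filter. For 26 vs 4 weeks it was 65 without 4-week replicate 2, 16 and 3 without 26-week replicates 1 and 2, and for 86 vs 26 weeks 205 and 324 without 26-week replicates 1 and 2, and 421 and 586 without 86-week replicates 1 and 2.

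**Figure D4:**
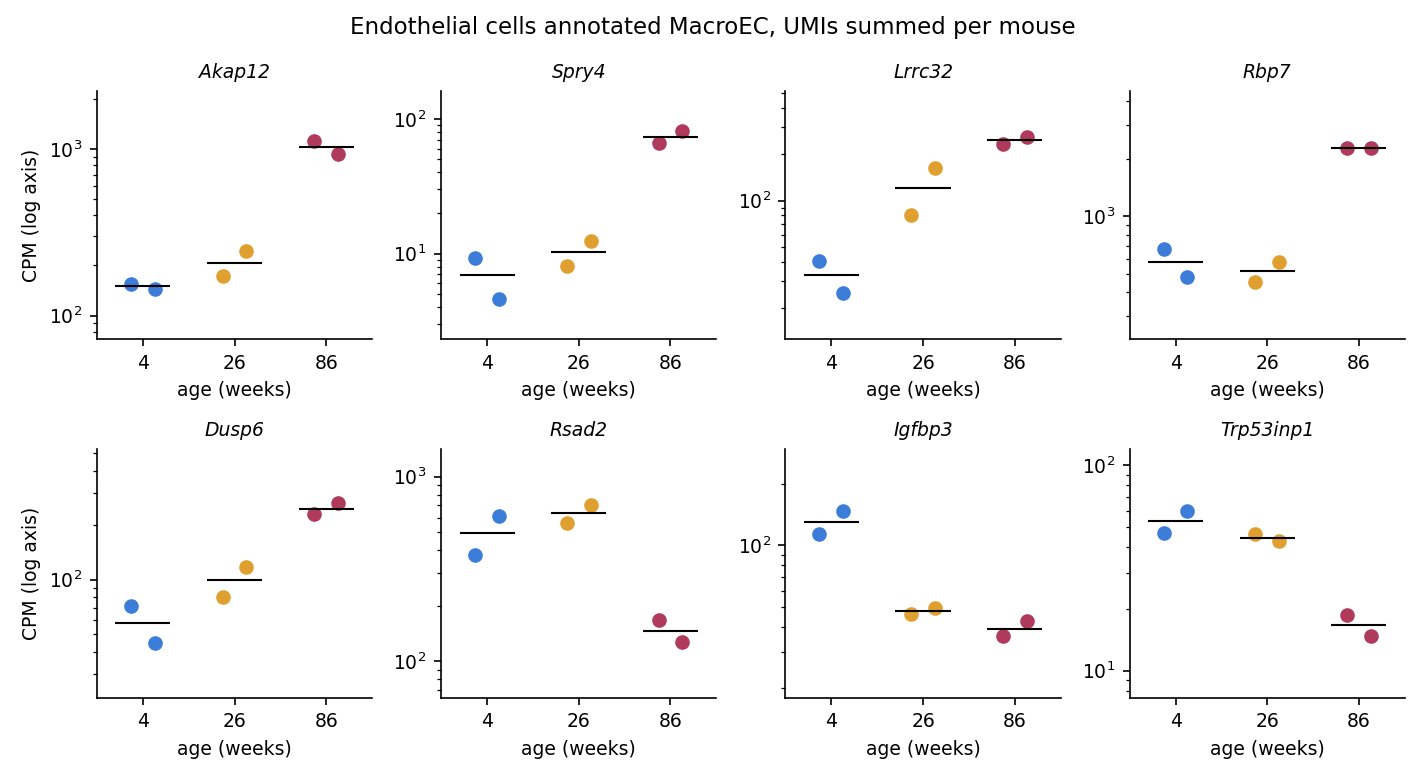
TMM-scaled CPM (y axis, log scale) of 8 genes in the summed MacroEC cells of each mouse against age (x axis, weeks). Points are single mice and lines are means of 2; Akap12 lies at 150 CPM at 4 weeks and 1027 CPM at 86 weeks.

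Macrophages gave no called gene over 11946 tested with edgeR between any pair of ages, with 1184, 1084 and 663 genes at an unadjusted p under 0.05 for 86 vs 4, 26 vs 4 and 86 vs 26 weeks and 196, 104 and 77 called by DESeq2. Adjusted over the list alone, 13 of 32 interferon-stimulated genes fell and 1 rose between 4 and 86 weeks, with Rsad2 at -1.54 ± 0.20 and Ifit2 at -2.13 ± 0.45 (median -0.65, camera adjusted p = 9.81e-07; adjusted p = 0.543 with an estimated correlation). Of 26 immediate-early genes, which respond within minutes to stimuli including tissue dissociation, 10 rose and 1 fell adjusted over the list alone, with Socs3 at 1.75 and Cebpd at 1.51 (adjusted p = 7.37e-07; adjusted p = 0.543 with an estimated correlation). Of 15 genes of resident and reparative macrophages none passed over the list alone, and the lectin genes Cd209f and Mgl2 had log2 changes of 1.24 and 0.66 (median 0.28, adjusted p = 0.00016; adjusted p = 0.543 with an estimated correlation). Over all genes, 0 members of these lists were called. Markers of other cells moved in the macrophage sums. Of 7 neutrophil markers 4 rose adjusted over the list alone (median 4.49, adjusted p = 0.00672; adjusted p = 0.543 with an estimated correlation), and of 10 fibroblast markers 3 fell (median -1.73, adjusted p = 0.000629; adjusted p = 0.547 with an estimated correlation). Adjusted over the list alone, 5 of 6 erythroid markers fell (median -7.93, adjusted p = 0.000353) and 4 of 5 striated muscle markers (adjusted p = 0.000353), and log2 changes were negative in 9 of 10 B-cell (median -1.20, adjusted p = 0.000353) and 9 of 9 T and NK cell markers (median -2.16, adjusted p = 0.000785). With an estimated correlation these 4 had an adjusted p of 0.543. Over the list alone adipocyte markers fell in 3 of 9 (adjusted p = 0.0219; 0.648 with an estimated correlation), and 1 of 8 smooth muscle markers rose while 7 had negative log2 changes (adjusted p = 0.0186; 0.543 with an estimated correlation). For 86 vs 4 weeks 3 genes were called without either 26-week mouse and 2 without 86-week replicate 2. For 26 vs 4 weeks 3 were called without either 26-week mouse, and for 86 vs 26 weeks 4 without 26-week replicate 2 and 3 without 86-week replicate 2.

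Whether the change from 4 to 86 weeks differed between classes was tested directly. Against fibroblasts, 947 of 13046 genes changed differently in smooth muscle cells, 334 with a more positive and 613 with a more negative change. Nov, a matricellular protein of the CCN family, fell in smooth muscle cells (log2 change -5.29) and rose in fibroblasts (1.47; difference -6.82 ± 0.38, adjusted p = 0.000106). Limch1, an actomyosin regulator, fell in smooth muscle cells (-6.36), while its change in fibroblasts, 0.43, did not pass (difference -6.91 ± 0.42, adjusted p = 0.000106). Gas1, a membrane protein of Hedgehog signalling, rose in smooth muscle cells (2.48) and fell in fibroblasts (-0.84; difference 3.27 ± 0.37, adjusted p = 0.0019). Against endothelial cells 193 of 12981 genes differed, 50 more positive and 143 more negative in smooth muscle cells, led by Limch1 (-6.34 ± 0.45, adjusted p = 0.0105) and the nonmuscle myosin Myh10 (-4.55 ± 0.34, adjusted p = 0.0105). The number of genes whose change from 4 to 86 weeks differs between smooth muscle cells and fibroblasts was 466 without 4-week replicate 2, 414 without 86-week replicate 2 and 1434 with no expression filter. Against endothelial cells it was 99 and 40 without 4-week replicates 1 and 2, 598 and 601 without 26-week replicates 1 and 2, 0 without either 86-week mouse and 401 with no expression filter.

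The open chromatin of the aorta was compared between ages through the peak lists of the 6 ATAC libraries. These held 129549 and 111093 peaks over 128.7 and 109.2 megabases at 4 weeks, 104661 and 108177 over 91.8 and 100.2 at 26 weeks, and 104405 and 97721 over 94.2 and 85.6 at 86 weeks. Sharing within ages and between ages differed by less than the spread between pairs. The mean Jaccard index was 0.712 ± 0.0928 (SD over 3 pairs) within ages and 0.711 over the 12 pairs between ages, a difference of 0.0013 (one-sided exact permutation of the pairing, p = 0.533, 8 of 15 pairings as large; smallest possible p 0.0667). Both libraries of an age always differ in replicate number, and pairs of different ages shared 0.742 ± 0.0512 with the same number and 0.679 ± 0.0463 with different numbers (6 pairs each). Over pairs of different numbers alone, a comparison chosen after the data had been seen, the difference was 0.033 (exact permutation, p = 0.333, 2 of 6 pairings as large). The 26-week pair shared 0.786, the 4-week pair 0.742 and the 86-week pair 0.608, the lowest of the 15 pairs. The highest, 0.792, joined 26-week replicate 1 and 86-week replicate 1. Between ages the mean was 0.729 ± 0.0438 for 4 and 26 weeks, 0.742 ± 0.0491 for 26 and 86 weeks and 0.660 ± 0.0499 for 4 and 86 weeks, each over 4 pairs. For the peaks of open chromatin shared within and between ages, the difference turned negative without either 4-week library (-0.0302 and -0.0128) and without either 26-week library (-0.0308 and -0.0158), and with peaks matched by at least 1 base (-0.0048) or by a reciprocal overlap (-0.0076).

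**Figure D5:**
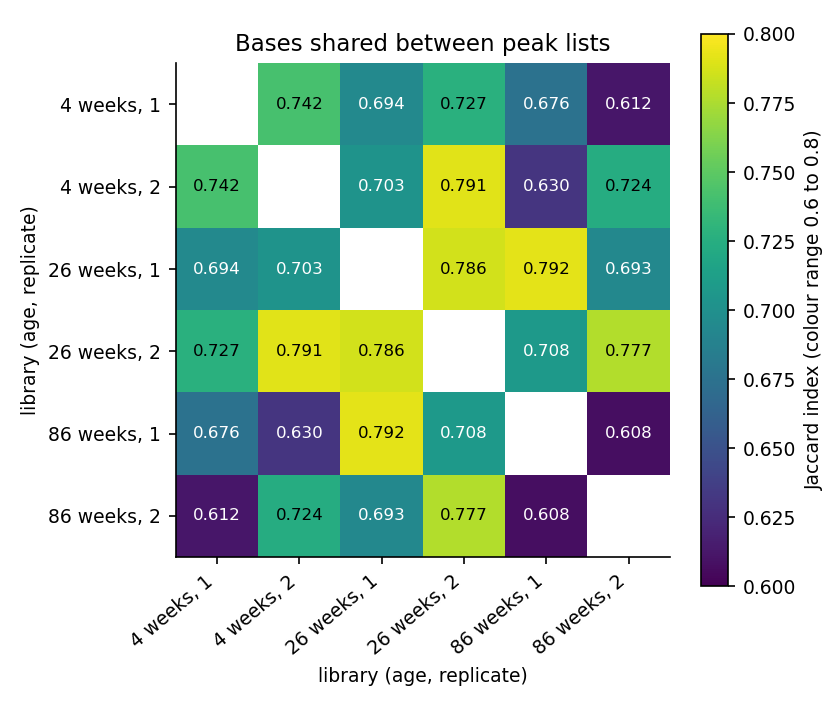
Jaccard index of bases covered by peaks for each pair of ATAC libraries, labelled by age and replicate on both axes, with colours from 0.6 to 0.8. The lowest value, 0.608, is that of both 86-week libraries.

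Accessibility at the genes that changed in the RNA was read from the 3 libraries with analysed count matrices, 1 at 26 weeks and 2 at 86 weeks, holding 95021857, 94391742 and 48042930 counts. With 1 library at 26 weeks, there was no test. At Sost, peaks at the gene ends had 19.5 CPM in the 26-week library and 18.9 and 13.5 CPM in 86-week replicates 1 and 2. They covered chromosome 11, 101962817 to 101966109 and 101966878 to 101967417, in the 26-week library. At Eln the values were 62.5, 62.5 and 19.2 CPM, under 3 peaks in the 26-week library and 1 in 86-week replicate 2. At Myh11 they were 18.3, 19.2 and 9.1 CPM. Peaks were called separately per library, and the lower CPM of replicate 2 went with fewer covered bases. These were 3833, 3919 and 2128 at Sost, 7436, 6441 and 1730 at Eln, and 2677, 3335 and 1927 at Myh11. Over 650 genes that fell in smooth muscle cells between 26 and 86 weeks, the median log2 ratio to the 26-week library was 0.02 in replicate 1 and -0.23 in replicate 2, above all and below all of 10000 matched random lists. Over 273 genes that rose it was 0.03 and -0.01, again above all and below all random lists. The peaks called per library differed too. At the falling genes they covered a median of 2562 bases in the 26-week library, 2645 in replicate 1 and 2147 in replicate 2. At the rising genes these were 2761, 2826 and 2585 bases. The 86-week libraries also differed in markers of cell types. Peaks at smooth muscle markers had a log2 ratio of 0.0038 in replicate 1, over 25548 covered bases, and of -1.14 in replicate 2, over 12950, against 24693 in the 26-week library. For B-cell markers the ratios were -0.84 over 10491 bases and 1.33 over 53455, against 22743. Cells of all types were pooled in these values.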

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

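The tests on pericyte-list cells and on fold changes in them, on thinned sums, on endothelial RNA, on fibroblasts of at least 3000 UMIs, on MacroEC cells alone and on equal numbers of each endothelial label were chosen only after the result they address was seen.

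What drew attention was a difference between cell classes in the change from 4 to 86 weeks, tested as an interaction in edgeR. It passed for 947 genes between smooth muscle cells and fibroblasts and for 193 between smooth muscle cells and endothelial cells. Against fibroblasts, the log2 change in smooth muscle cells was higher by 3.75 ± 0.66 (SE) for Fabp4 (adjusted p = 0.0276), 3.37 ± 0.55 for Tsc22d3 (0.0239), 3.34 ± 0.52 for Tmem204 (0.00894), 3.27 ± 0.37 for Gas1 (0.0019) and 2.98 ± 0.58 for Nrp1 (0.0441). Limch1 (-6.91 ± 0.42, adjusted p = 0.000106), Nov (-6.82 ± 0.38, 0.000106) and Efhd1 (-6.41 ± 0.58, 0.00118) differed the other way. Vcan (-13.25 ± 1.51, adjusted p = 0.00474) and Sema3d (-11.66 ± 1.97, 0.015) had no UMI in smooth muscle cells at 86 weeks, so their differences come from the model and are no bound. Against endothelial cells, the change was higher by 3.58 ± 0.32 for Arhgdib (adjusted p = 0.0107), 3.34 ± 0.55 for Gstt2 (0.0449), 3.18 ± 0.33 for Abcg2 (0.0127), 2.71 ± 0.36 for Mgst1 (0.0267) and 2.63 ± 0.38 for Tcp11l2 (0.0303). It was lower for Limch1 (-6.34 ± 0.45, adjusted p = 0.0105), Myh10 (-4.55 ± 0.34, 0.0105), Fam198b (-4.52 ± 0.49, 0.015), Phactr1 (-4.49 ± 0.43, 0.0107) and Tes (-4.16 ± 0.46, 0.015).

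The first pattern weighed is the 1276 genes that differed in smooth muscle cells between 4 and 86 weeks. The lower summed UMIs of the 86-week mice as the whole cause are argued against, since 681 of 963 calls (0.707) tested in sums thinned to the lowest were called again in the same direction. Endothelial RNA in the droplets would bring all endothelial transcripts at 1 share of their endothelial level, which argues against it for Esam and Fabp4. They stood at 35.2% and 50.1% in 86-week replicate 1, beside no UMI of Pecam1 and 0.525% for Cldn5. In replicate 2 they stood at 56.7% and 43.3%, and shares differed 18.9-fold from Esam to Vwf (1 UMI). There, 3.03% for Kdr (7 UMIs) and 4.66% to 15% for 6 other markers leave a smaller amount of such RNA open. Different mixtures of cells under the smooth muscle label at the 3 ages and a change of the cells with age cannot be told apart, since the split into pericyte-list cells rests on markers that themselves rose with age. An Acta2 UMI was found in 56.5% and 48.4% of the 86-week cells under this label, against 81.6% to 95% in the younger mice. For Myh11 these were 47.8% and 58.1% against 82.4% to 94%. The 86-week cells were also shallower, with medians of 3580 and 6306 UMIs. Pericyte-list cells gave 0.29 times the calls of as many cells drawn at random, 359 against 1239, but with a larger spread (BCV 0.218 against 0.181). Their log2 changes were a median of 0.736 times (390 rising genes) and 0.933 times (733 falling genes) as large. These ratios cover called genes with a UMI at both ages in both sets, which leaves out genes such as Sost. At 86 weeks each set held 32 of 46 and 29 of 31 cells, so the ratios compare largely the same old cells.

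The second pattern is the fall of matrix transcripts in fibroblasts between 4 and 86 weeks. Low-UMI barcodes kept in 4-week replicate 1 are argued against as its cause, since 10 of the 10 named falling genes were called in the same direction among cells of at least 3000 UMIs. Smooth muscle RNA in the droplets of the 4-week fibroblasts would account for at most 3.05% of the fibroblast level, reached by Col4a5 in replicate 1. An effect of age stays open as a hypothesis, as do differences between fibroblast types recovered at each age, and neither was tested.

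The third pattern is that edgeR called no gene in all endothelial cells (1928 with an unadjusted p under 0.05, 275 by DESeq2) and 966 in MacroEC cells between 4 and 86 weeks. For mixing of endothelial types in the sums, as many endothelial cells drawn at random gave 0 calls, which decides nothing, since the pool they came from gave 0 too. Proportions of the 3 endothelial labels that differ between mice cannot be told apart from other sources, since equal numbers of each label in every mouse (362 MacroEC, 25 LymphoEC and 21 MicroEC cells) gave 445 calls, 0.461 times those of MacroEC cells, between the bounds set before this test. Within the MacroEC label expression was tested with age, and the 966 calls are differences between 4 and 86 weeks under that label. Whether cells under the MicroEC and LymphoEC labels change with age was not tested for either label alone.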

How the results depend on the processing

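Tests on cells of at least 3000 UMIs, on pericyte-list or randomly drawn cells, on MacroEC, B and T cells, on equal numbers of each endothelial label and on peak pairs of different replicate numbers were chosen after the data were seen. Of 3394 values under alternatives, 2642 kept their direction and call or moved little. No named gene turned its direction. The naming rule took only genes with both mice of 1 age above both of the other. Runs without 1 of these mice are thus no separate support for the direction of the named genes. Of 951 of their values without a library left out 873 were kept and 78 missed the threshold, and of 864 with 1 left out 605 and 259. No class share passed its test under the alternatives with all 6 mice. A single class at the smallest possible p of the exact test, 0.0222, could not pass after adjustment over 14 classes. Shares with a mouse left out were not tested. Leave-one-out, the difference in share between 86 and 4 weeks turned sign in 6 of 14 classes, fibroblasts (-16.1 to 5.77 points), B cells (-19.8 to 11.6), CD4 T cells (-8.03 to 1.63), CD8 T cells (-5.05 to 4.96), mast cells (-0.0542 to 0.312) and pericytes (-0.054 to 0.299). For gene lists 143 of 290 and 736 of 870 were kept, and 11 turned sign. Counts of calls were kept in 56 of 99 and 41 of 72 values in the main classes. Where a count moved, the cause was not tested. Shares over all barcodes were not run, since unlabelled barcodes carry no class.

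Counts below are in the order 86 vs 4, 26 vs 4 and 86 vs 26 weeks. They were 1276, 4 and 992 in smooth muscle cells, 537, 211 and 2 in fibroblasts, 0, 0 and 0 in endothelial cells and in macrophages, and 966, 137 and 1026 in MacroEC cells. For 86 vs 4 weeks they were 0 in B cells, 40 in CD4 and 178 in CD8 T cells. With no filter on low counts they were 2482, 384 and 2219 in smooth muscle cells, 1186, 772 and 383 in fibroblasts, 114, 13 and 153 in endothelial cells, and 78, 33 and 24 in macrophages. DESeq2 called 72 for 26 vs 4 weeks in smooth muscle cells, 841, 546 and 204 in fibroblasts, 275, 57 and 307 in endothelial cells, 196, 104 and 77 in macrophages, 241 for 26 vs 4 weeks in MacroEC cells, and 123, 221 and 88 in B, CD4 and CD8 T cells.

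Also with no filter on low counts, genes changed in MacroEC cells, 86 vs 4 weeks, were 2089, genes changed in MacroEC cells, 26 vs 4 weeks, 800 and genes changed in MacroEC cells, 86 vs 26 weeks, 1788. The genes changed in B cells, 86 vs 4 weeks, were 929, genes changed in CD4 T cells, 86 vs 4 weeks, 922 and genes changed in CD8 T cells, 86 vs 4 weeks, 516. The genes whose change from 4 to 86 weeks differs between smooth muscle cells and fibroblasts were 1434 in place of 947, and against endothelial cells 401 in place of 193.

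Thinned to the lowest sum, 6 were called in fibroblasts for 86 vs 26 weeks, 1 in endothelial cells for 86 vs 4 and 1 for 86 vs 26 weeks, and 55 in CD8 T cells. Without Scrublet doublets, 15 were called in fibroblasts and 1 in endothelial cells for 86 vs 26 weeks, 5 in B and 66 in CD4 T cells. Only cells with at least 3000 UMIs gave 2 in smooth muscle cells for 26 vs 4 and 25 in fibroblasts for 86 vs 26 weeks. Only cells with pericyte-list UMIs gave 359, 0 and 299 in smooth muscle cells. Smooth muscle cells drawn at random gave 2 for 26 vs 4 weeks, and endothelial cells drawn at random 1 for 26 vs 4 and 7 for 86 vs 26 weeks. Equal numbers of each endothelial label gave 445, 33 and 532. Only MacroEC cells in place of all endothelial cells gave 966, 137 and 1026.

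By their names, mice of different ages share only a replicate number. Some cell shares went with it. B cells were 12.3%, 19.6% and 4.33% in replicates 1 at 4, 26 and 86 weeks, and 35.9%, 31.7% and 35.7% in replicates 2. Fibroblasts were 37.3%, 27.6% and 32.2% against 15.6%, 17% and 10.3%. Endothelial cells kept no such order, with 15.2%, 8.24% and 26% against 9.91%, 11.7% and 13.2%. Expression deviations of same-numbered mice from the age means correlated by -0.471 to 0.624 over pairs of ages and classes. With the replicate number as a block, the count was 0 for 26 vs 4 weeks in smooth muscle cells, 1 for 86 vs 26 weeks in fibroblasts, 64 for 26 vs 4 weeks in MacroEC cells, and 2, 125 and 420 in B, CD4 and CD8 T cells. The block moved no other count by over 1.5 times. It ended 15 of 144 calls of named genes.

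Leave-one-out fits keep 1 mouse at an age, and the lone sample is assumed to vary like the other groups. Their counts went from 312 to 1469, 0 to 13 and 440 to 1396 in smooth muscle cells, 84 to 515, 6 to 385 and 2 to 101 in fibroblasts, 0 to 3, 0 to 3 and 0 to 4 in macrophages, and 376 to 725, 3 to 154 and 205 to 1116 in MacroEC cells. They went from 0 to 2023 in B cells, 0 to 1068 in CD4 and 49 to 295 in CD8 T cells, and from 414 to 1196 and 0 to 601 for the differences against fibroblasts and endothelial cells.

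Of 144 gene list tests that passed in camera, 0 passed with the estimated correlation, and 139 to 218 passed leave-one-out. The direction of camera turned leave-one-out for 11 lists, given with their medians. They were, in fibroblasts for 86 vs 4 weeks, cell cycle (1.05; -0.246 to 1.90) and MHC class II (-0.173; -2.62 to 0.714). In endothelial cells for 26 vs 4 weeks they were fibroblast markers (-2.18; -3.03 to 0.666), adipocyte markers (-1.09; -1.51 to 0.356) and chemokines (0.405; -0.165 to 1.66). The elastic fibre (-0.641; -1.56 to -0.18), complement (-0.723; -1.39 to -0.0275) and oxidative phosphorylation lists (-0.22; -0.351 to -0.0375) turned there with medians below 0. In macrophages they were MHC class I (-0.227; -0.883 to 0.133) and ER chaperones (0.176; -0.169 to 0.485) for 86 vs 4 and neutrophil markers (2.20; -0.278 to 2.96) for 86 vs 26 weeks. Medians alone crossed 0 for adipocyte markers in macrophages (86 vs 4 weeks, -1.41 to 0.0424), for chemokines in smooth muscle cells (86 vs 4 weeks, -1.75 to 3.53), fibroblasts (86 vs 4 weeks, -0.374 to 1.36) and macrophages (26 vs 4 weeks, -0.0098 to 0.593), and for fibrillar collagens (-2.53 to 0.0439) and matrix proteases (-0.973 to 0.157) in endothelial cells (26 vs 4 weeks).

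For the peaks of open chromatin shared within and between ages, the difference of 0.0013 was -0.0048 with peaks overlapping by at least 1 base, -0.0076 with reciprocal overlap, 0.033 over pairs of different replicate numbers, and -0.0308 to 0.0488 leave-one-out. Over the gene body plus 1000 bases, the median log2 ratio for genes that rose in smooth muscle cells was -0.0541 for 86 vs 26 weeks in library 2 (main -0.0084), and for 86 vs 4 weeks 0.0305 in library 1 (main 0.0172) and -0.0693 in library 2 (main -0.00097). The last was 0.00125 within 2000 bases. For genes that fell there, library 1 had 0.0414 for 86 vs 26 (main 0.0185) and 0.0262 for 86 vs 4 weeks (main 0.0106) over the gene body.

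Depth limits what was seen in smooth muscle cells, with 196078 and 203451 UMIs at 86 weeks, where 3 counts over both mice correspond to 6.62 CPM.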

Other observations

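The tests of MacroEC cells, T cells and B cells were chosen after the data were seen.

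In T cells of the aorta some genes were called between 4 and 86 weeks. The sums of 86-week replicate 1 came from only 61 CD8 and 70 CD4 T cells, with 428636 and 417862 UMIs. The other mice held 310 to 514 CD8 and 338 to 653 CD4 T cells. In CD8 T cells, Gzmk, a granzyme of cytotoxic cells, rose from 5.76 to 115 CPM (log2 change 4.08 ± 0.51, SE, edgeR adjusted p = 0.0335), and Ccl5, a chemokine of effector T cells, from 2375 to 10080 CPM (2.08 ± 0.23, adjusted p = 0.00584). Gzmm (1.73) rose too. Ccr9, a receptor for the chemokine CCL25, fell from 90.6 to 16.8 CPM (-2.40 ± 0.18, adjusted p = 8.68e-05), as did Id3 (-1.61) and Dnmt3a, a DNA methyltransferase (-1.14). Of 9920 genes 178 were called, 139 higher and 39 lower, and DESeq2 called 88. The count was 49 and 51 without 4-week replicates 1 and 2, 295 and 277 without 86-week replicates 1 and 2, and 55 with sums thinned to the lowest. In CD4 T cells 40 of 10271 genes were called, 25 higher and 15 lower, and none without 4-week replicate 1 or either 26-week mouse. Casp4 (2.87, adjusted p = 0.0199), Cxcr3 (2.17), Socs3 (2.13) and Maf (1.86) rose, and Sox4 (-2.60, adjusted p = 0.0185), Satb1 (-1.66) and Bach2 (-1.21) fell. In B cells edgeR called none of 11043 genes, with 1397 at an unadjusted p under 0.05 and 123 called by DESeq2. Of 30 cell cycle genes 23 were higher in B cells at 86 weeks adjusted over the list alone, with Pclaf at 4.56 and Top2a at 1.53 (median 0.92, camera adjusted p = 2.51e-16; adjusted p = 0.726 with an estimated correlation). Top2a was at 10.5 and 7.98 CPM in the 4-week mice and 29.6 and 24.0 CPM in the 86-week mice. The B cells of 86-week replicate 1 stood apart, with 126 cells at a median of 9712 UMIs against 726 to 1717 cells at 3776 to 4580 UMIs. The same comparison had positive log2 changes in 36 of 36 ribosomal genes (median 0.34, adjusted p = 1.65e-16), 13 of 13 mitochondrially encoded genes (median 0.36, adjusted p = 1.58e-09), 9 of 9 macrophage markers (median 1.65, adjusted p = 0.377) and 9 of 9 inflammatory macrophage genes (median 1.97, adjusted p = 0.0535). They were negative in 8 of 8 smooth muscle markers (adjusted p = 0.000109), 10 of 10 fibroblast markers (adjusted p = 0.00039) and 16 of 17 contractile genes (adjusted p = 2.61e-06). With an estimated correlation the adjusted p of these lists were 0.726 to 0.806.

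A part of the clock genes was called in MacroEC cells. The hour of tissue collection was not part of any fit, so a difference in it between ages cannot be told apart from age. Of 16 circadian genes 1 rose and 2 fell from 4 to 26 weeks (camera adjusted p = 0.00901; adjusted p = 0.943 with an estimated correlation), and 4 rose and 1 fell from 26 to 86 weeks (0.0383; 0.948 with an estimated correlation). In the first of these comparisons 2 of 5 striated muscle markers were called as falling (camera adjusted p = 3.48e-05), log2 changes were negative in 10 of 10 fibroblast markers with none called (0.0249), and of 26 immediate-early genes 19 had positive log2 changes with none called, while 2 fell adjusted over the list alone (0.0202). In the second 1 of 9 pericyte markers was called as falling (0.0397). These lists had 0.943 and 0.948 at the estimated correlation. Per2 fell with a log2 change of -2.86 and Arntl rose with 1.04 from 4 to 26 weeks, and from 26 to 86 weeks Per2 (2.56) and Cry1 (2.21) rose and Arntl (-1.49) fell. In macrophages no gene was called over all genes, and 7 of 14 circadian genes rose and 1 fell from 26 to 86 weeks adjusted over the list alone, with Nr1d2 at 1.51 (median 0.69, camera adjusted p = 1.18e-05; adjusted p = 0.556 with an estimated correlation).

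Cells labelled MacroEC expressed Cd36 at 7592, 6052 and 6800 CPM and Vwf at 60.6, 88.9 and 93.6 CPM at 4, 26 and 86 weeks. Those labelled MicroEC had Cd36 at 1986, 2148 and 2911 CPM and Vwf at 2890, 2278 and 2258 CPM. Cd36, a fatty acid transporter abundant in capillaries, was thus higher under the MacroEC label and Vwf, abundant in large vessels, under the MicroEC label, the reverse of what the names say. Cells labelled pericytes had the endothelial genes Pecam1 at 909, 827 and 962 CPM and Cdh5 at 1022, 1181 and 1534 CPM, which a pericyte should lack. The labels were kept as the authors gave them.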
